A study of Macaca nemestrina with 10 samples.

How the data were processed

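Total RNA from pieces of chorioamnion, the fetal membranes, was measured in 10 pregnant pigtail macaques (Macaca nemestrina), 1 array per animal. Per the labels, 5 animals had received Group B Streptococcus (GBS) into the choriodecidua, the space between the membranes and the uterine lining, and 5 had received saline. The piece was taken at the inoculation site 4 days after GBS and 7 days after saline, so the day and the inoculation cannot be told apart. The labels call the tissue amniotic epithelium, while the series design calls it chorioamnion. No batch, scan date or pairing was given in the labels used here, and replicate numbers follow the order of deposition and pair nothing.

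Per the submitters' processing notes, the values were made with RMA (robust multi-array average: background correction, normalization between arrays and summary per probe set on a log2 scale), with no version given in the sources used here. The authors deposited log2 values for 52779 probe sets of the Affymetrix Rhesus Macaque Genome Array, a design based on a related species (Macaca mulatta). A probe that mismatches the pigtail macaque transcript would read low in both groups. Array medians lay between 4.49 and 4.59, and correlations between arrays between 0.903 and 0.986, so no array was a copy of another. No detection calls or scanner intensities were analysed here, so the signal over background of single probe sets is unknown. The number of arrays limits the precision. RMA log2 differences of dim probe sets understate true ratios.

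Gene symbols came from the platform annotation table. Of the probe sets other than 13 array controls, 24956 had 1 symbol, 361 had several and 27449 were not listed. The RefSeq gene table of the pigtail macaque shared no gene identifiers with the annotation, so symbols were kept as given and no coordinates are reported. Symbols starting with LOC are unnamed loci. Probe sets with 1 symbol were kept, and each gene was represented by its probe set with the highest mean over all 10 arrays. Genes whose mean lay above the median of all probe sets other than controls, 4.56 on the log2 scale, were tested, which left 10044 genes of 14132. The same filter left 26383 probe sets for a second fit without gene symbols.

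Differences are GBS minus saline on the log2 scale. They were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) over 10 arrays with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error (SE) of a gene's difference is the moderated one from that fit. The 29 gene lists hold 830 entries, of which 612 were named on the array and 489 passed the filter. They were tested with camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the 29 lists. Beside it stand camera with the correlation estimated from the residuals, fry, and an exact two-sided permutation test of the list's mean per animal over the 252 assignments of 10 animals. The smallest p that test can give is 0.00794. Members of each list were adjusted over the list alone and over all genes. The p-values of single genes, of fry and of the permutation test measure the spread between these animals. Camera compares a list's genes with all other genes. At the preset correlation its p does not measure the spread of a list mean between animals. It comes out too small where members move together, as in the desmosome list (estimated correlation 0.84). The lists, the tests, the filter, the main alternatives and the rule for named genes were fixed before the data were examined.

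The rule for named genes took the 14 genes with the largest rise and the 14 with the largest fall past the adjusted threshold with no overlap between groups. With fewer than 5 passing in a direction, as here in both, it took the 14 with the smallest unadjusted p among differences of at least 1 log2 unit. It also took up to 4 members of each list with the largest absolute difference, and every cytokeratin past the adjusted threshold, of which there were 0. It named 135 distinct genes.

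The gene fit, whose function also fitted the probe sets, was tested on simulated data with the residual spread of the real 10044 genes and 200 genes changed, drawn independently of one another over 10 runs. For GBS minus saline the simulated fit recovered 54.5% of genes changed 2-fold, 83.4% of those changed 4-fold and 97.0% of those changed 16-fold, with 4.8% false calls. In a single simulated data set the camera step called 0 of 29 lists with nothing changed, and 1 when the cytokeratins alone were lowered. The simulation gave genes no correlation with each other, which the real arrays have, and held no arrays standing apart. Its changed genes were drawn from all genes tested, whose median SE was 0.21. The recovery therefore does not carry over to genes with a larger SE, such as KRT24 (0.85).

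Alternatives were no filter and a stricter filter on dim probe sets at the 75th percentile, each array centred on its median, quantile normalization repeated, a trend and robust variance in eBayes, array weights, the mean of all probe sets of a gene, other thresholds, an unequal-variance test per gene, other list tests, and leaving out each array. Fits without the arrays that stood apart and a fit with a tissue covariate were added after seeing the data.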

Results

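The series measured transcripts in the fetal membranes of 10 pregnant pigtail macaques, 5 inoculated with GBS, a bacterium that can ascend from the lower genital tract, and 5 with saline. Each animal gave 1 array of log2 RMA values. The comparison asks which transcripts of the membranes at the inoculation site differ after GBS, and the series title names the cytokeratins, the keratins of epithelial cells. Tissue was taken on day 4 after GBS and day 7 after saline.

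The arrays did not divide cleanly by group. The first principal component held 42.7% of the variance and the second 17.4%. GBS replicate 5 lay at 73.5 on the first component, the other 4 GBS arrays lay from -39.5 to -20.2, and saline replicate 3 lay at 67.1. The group means on it were -12.1 ± 48.5 and 12.1 ± 33.2 (SD, n = 5 each, exact permutation p = 0.389, two-sided). In GBS replicate 5 the trophoblast and red cell lists stood highest of the 10 arrays, at 1.65 and 3.27 log2 units above the mean of all arrays. Saline replicate 3 came next in both, at 1.07 and 1.03. On the second component GBS replicate 5 lay at 50.3 and saline replicate 2 at -49.9, and saline replicate 2 had the interferon-stimulated list at 1.88. The 3' to 5' log2 ratios of the array's control probe sets overlapped between groups, at 1.01 ± 0.39 after GBS and 0.79 ± 0.24 after saline for GAPDH (SD, n = 5 each, exact permutation p = 0.373, two-sided). GBS replicate 5 had the highest GAPDH ratio, 1.65.

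**Figure D1:**
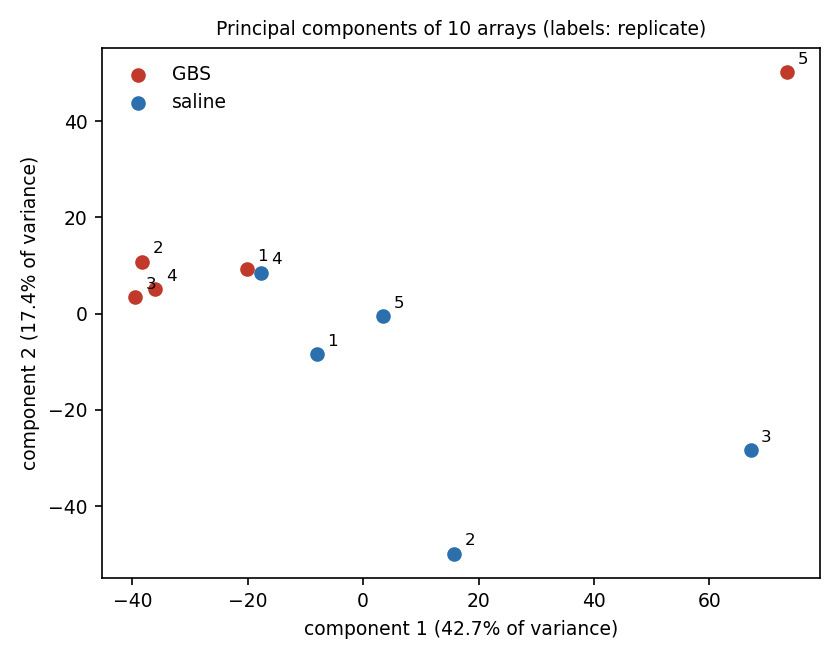
First and second principal components (arbitrary units, percent of variance on the axes) of the 10 arrays over 10044 genes, 1 point per animal, coloured by inoculation and numbered by replicate. GBS replicate 5 and saline replicate 3 sit at 73.5 and 67.1 on component 1, while the other 4 GBS arrays lie between -39.5 and -20.2.

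Of 13 measured cytokeratins, 5 fell after GBS when adjusted over the list alone and 8 did not pass, and 0 passed when adjusted over all 10044 genes. KRT24, a type I keratin, differed by -5.90 ± 0.85 log2 units (SE, n = 5 per group). KRT3, a type II keratin, differed by -5.30 ± 0.78 on its brightest probe set. In GBS animals 3 of 5 KRT24 values, 4 of 5 KRT3 values and 2 of 5 KRT9 values lay below the dim-filter level, so no fold is given for these genes. KRT9 differed by -3.75 ± 0.82 and KRT19, a keratin of simple epithelia, by -2.97 ± 0.73. In each of these 4 genes and in KRT16 every GBS animal lay below every saline animal. The fifth, KRT16 (-2.65 ± 0.68), was added after its values were seen, because it completes that count.

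The other 8 cytokeratins did not pass, and the 4 named here were chosen after their values were seen. KRT7 and KRT8, both of simple epithelia, differed by -1.60 ± 0.94 and -1.77 ± 0.75 and overlapped between groups, and KRT18, the usual partner of KRT8, differed by 0.80 ± 0.59. KRT10 differed by 0.03 ± 0.21. The mean over the list was -1.73 log2 units and its median -1.60, against -0.68 and -0.05 without the filter on dim probe sets. The list mean of all 5 GBS animals lay below that of every saline animal. The list was called lower by camera (adjusted p = 9.2e-06), but with an estimated correlation its adjusted p = 0.198, and its exact permutation p of 0.00794 is the smallest possible and adjusts to 0.230 over the lists. Without GBS replicate 5 and saline replicate 3, a choice made after seeing the data, its adjusted p = 0.0445 with an estimated correlation, the only such call over all lists and alternatives run. Because the series title names the cytokeratins, the list was not chosen independently of the study, and its fall is not independent evidence. KRT3 had 3 probe sets above the filter, with differences of -5.30, 0.02 and -1.14, so which keratin its brightest probe set reads is uncertain. KRT16 had 4, with differences of -2.65, 0.10, -3.85 and -0.52, and is uncertain too. Of 54 cytokeratin genes listed, those without a probe set of 1 symbol above the filter are not analysed here.

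**Figure D2:**
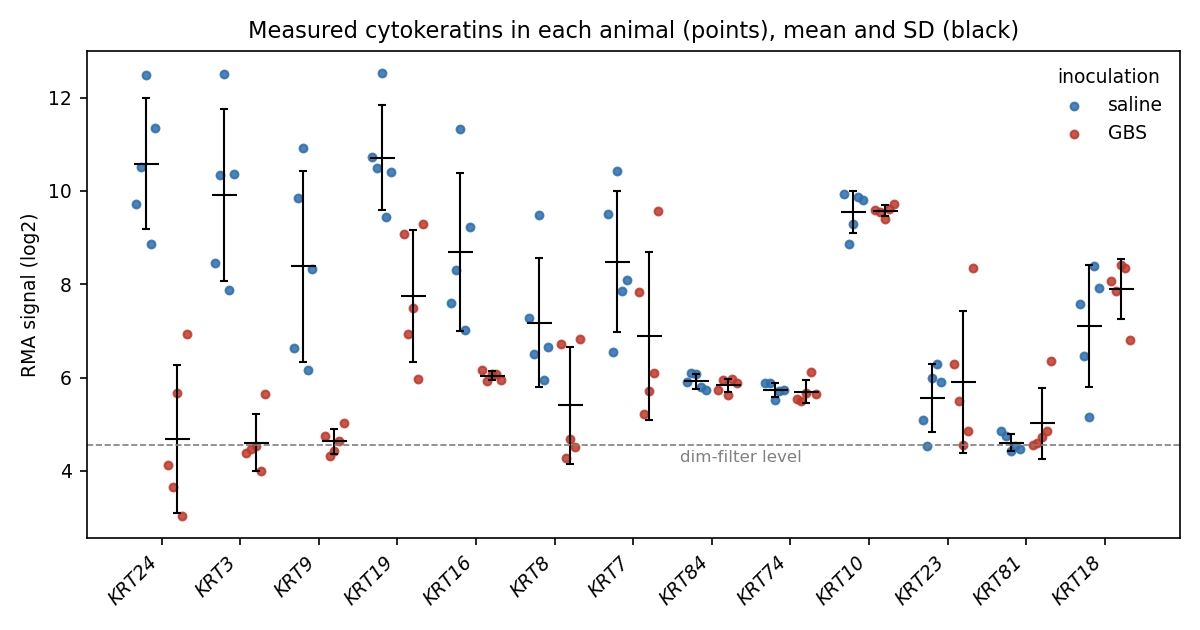
RMA signal (log2) of the 13 measured cytokeratins, 1 point per animal, ordered by the difference between groups, with the mean and SD of each group in black and the dim-filter level of 4.56 dashed. In KRT24, KRT3, KRT9, KRT19 and KRT16 all 5 GBS animals lie below all 5 saline animals, while KRT10 differs by 0.03.

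The desmosome and amnion epithelium lists were called lower by camera at its preset correlation. Of 6 measured desmosome genes, which encode the junctions that anchor keratin filaments, 5 fell when adjusted over the list alone and 1 did not pass. DSC2 differed by -3.79 ± 1.01, DSP (desmoplakin) by -3.54 ± 1.16, DSG2 by -3.17 ± 0.87 and PERP by -2.63 ± 0.84. Their values overlapped between groups, since GBS replicate 5 had DSP at 11.2, within the saline range of 9.46 to 12.2. DSG2 had another probe set above the filter at -0.03, and 4 of its 5 GBS values lay below the dim-filter level. The desmosome list was called lower (mean -2.52, camera adjusted p = 3.2e-07), with adjusted p = 0.209 with an estimated correlation. Of 7 measured amnion epithelium markers, 4 fell when adjusted over the list alone: GABRP (-3.45 ± 1.28), HAND1 (-2.67 ± 0.75), UPK1B (-2.49 ± 0.80) and ITGB6, an epithelial integrin (-2.26 ± 0.41). That list had a mean of -1.83 and camera adjusted p = 6.4e-05, with adjusted p = 0.198 with an estimated correlation. Without the filter on dim probe sets the desmosome mean was -1.67, and the amnion list had a mean of -1.09 and a median of -0.35, where its median with the filter was -2.26.

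Among 16 measured epithelial junction genes none passed when adjusted over the list alone. EPCAM, an epithelial adhesion molecule, differed by -2.89 ± 1.00, CLDN1 (claudin 1) by -2.10 ± 0.82, RAB25 by -1.75 ± 0.82 and CLDN4 by -1.05 ± 0.69. The list was called lower (mean -0.68, camera adjusted p = 0.0057), with adjusted p = 0.442 with an estimated correlation, and the call was lost without saline replicate 3 (mean -0.41, adjusted p = 0.14). Without the filter on dim probe sets its mean was -0.44. Of 19 cornified envelope genes none passed over the list alone. TP63 differed by -1.19 ± 0.67 and SFN by -0.95 ± 0.36, while S100A2 differed by 1.43 ± 0.52 and TGM3, a transglutaminase, by 1.09 ± 1.14. That list had a mean of -0.23 and camera adjusted p = 0.0107, with adjusted p = 0.299 with an estimated correlation, and its mean was 0.16 under the stricter filter on dim probe sets, -0.11 without saline replicate 3 and -0.15 without GBS replicate 5 and saline replicate 3.

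The lists of fibroblast matrix, basement membrane and hypoxia were called lower by camera at its preset correlation, with few members passing. Of 37 fibroblast matrix genes 1 fell when adjusted over the list alone, FN1 (fibronectin, -0.55 ± 0.12), named after its values were seen as the count of 1. LUM (lumican) differed by -3.52 ± 1.42, FBN2 by -2.23 ± 1.36, LOXL2 by -2.02 ± 0.64 and THBS1 by -1.53 ± 0.41. The list had a mean of -0.55 and camera adjusted p = 2.5e-04, with adjusted p = 0.256 with an estimated correlation, and the call was lost without saline replicate 2 (adjusted p = 0.0775). Of 20 basement membrane genes, LAMA3, a laminin chain of epithelial basement membranes, fell by 2.39 ± 0.55 when adjusted over the list alone and 19 did not pass. Its other probe sets above the filter lay at -0.14 and -0.34. COL7A1 differed by -1.75 ± 0.72, ITGB4 by -1.56 ± 0.53 and HSPG2 by -1.27 ± 0.45. This list had a mean of -0.38 and camera adjusted p = 0.0107, with adjusted p = 0.256 with an estimated correlation, and the call was lost without GBS replicate 5, saline replicate 2 and saline replicate 3 together (adjusted p = 0.0755). Its mean was -0.23 over the mean of all probe sets and -0.24 without GBS replicate 5 and saline replicate 3. In the hypoxia and glycolysis list 3 of 22 fell over the list alone, P4HA1 (-1.35 ± 0.34) and P4HA2 (-1.30 ± 0.26), both subunits of collagen prolyl hydroxylase, and EGLN1 (-0.60 ± 0.18), an oxygen sensor named as the rest of that count. The carbonic anhydrases CA12 and CA9 differed by -1.76 ± 0.89 and -1.20 ± 0.46. The list had a mean of -0.58 and camera adjusted p = 3.2e-07, with adjusted p = 0.209 with an estimated correlation. Without GBS replicate 5, saline replicate 2 and saline replicate 3 the mean was -0.24. P4HA1 had a second probe set, at 0.71.

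The lists of macrophage, T and NK cell and neutrophil markers were called higher by camera at its preset correlation, with 1 member passing. All 22 macrophage and monocyte markers had a positive difference, though none passed when adjusted over the list alone. MARCO, a scavenger receptor, differed by 1.60 ± 0.93, STAB1 by 1.28 ± 0.45, MS4A7 by 1.20 ± 0.50 and CD14 by 1.19 ± 0.66. The list had a mean of 0.76 and camera adjusted p = 6.5e-07, with adjusted p = 0.357 with an estimated correlation. The other 4 GBS arrays lay above all saline arrays in this list, while GBS replicate 5 lay at -1.07. Of 17 T and NK cell markers CD8A, the CD8 alpha chain, rose by 1.10 ± 0.22 when adjusted over the list alone and 16 did not pass. NKG7 differed by 1.40 ± 0.72, GZMH (granzyme H) by 1.38 ± 0.56, KLRC1 by 1.17 ± 1.14 and GZMB by 1.13 ± 1.27. That list had a mean of 0.56 and camera adjusted p = 0.0088, with adjusted p = 0.360 with an estimated correlation, and the call was lost under the stricter filter (adjusted p = 0.368). Its mean was 0.88 without GBS replicate 5 and 0.85 with saline replicate 2 and saline replicate 3 also left out. Of 16 neutrophil markers none passed over the list alone. CSF3R, the G-CSF receptor, differed by 1.87 ± 0.62, S100A9 by 1.32 ± 1.15, S100A8 by 1.32 ± 1.10 and G0S2 by 1.17 ± 0.95. The neutrophil list had a mean of 0.65 and camera adjusted p = 0.0276, with adjusted p = 0.530 with an estimated correlation, and the call was lost under the stricter filter (adjusted p = 0.0634). Its mean was 1.13 without GBS replicate 5, 1.09 with saline replicate 2 and saline replicate 3 also left out, 0.39 without GBS replicate 3 or GBS replicate 4, and 0.41 without saline replicate 3.

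Lists of innate signalling and early response genes were also called higher by camera at its preset correlation. Of 31 Toll-like receptor and NF-kappa-B genes none passed over the list alone. CD14 is also on this list, BIRC3 differed by 0.91 ± 0.78, TLR2 by 0.86 ± 0.74 and TNFAIP2 by -0.88 ± 0.35. The list had a mean of 0.35 and camera adjusted p = 0.0323, with adjusted p = 0.530 with an estimated correlation. Leaving out GBS replicate 3, GBS replicate 4, saline replicate 3, saline replicate 4 or saline replicate 5 ended the call of this list and of the neutrophil list, with adjusted p up to 0.34 in both. For this list so did no filter (adjusted p = 0.0932), the stricter filter (0.0587) and the mean of all probe sets (0.0938). Its mean was 0.21 without GBS replicate 3, 0.61 without GBS replicate 5 and 0.67 with saline replicate 2 and saline replicate 3 also left out. Of 17 interleukin 6 and STAT3 genes IL6R, the interleukin 6 receptor, rose by 1.33 ± 0.32 over the list alone and 16 did not pass. BCL3 differed by 0.74 ± 0.24, CEBPB by 0.74 ± 0.38 and HP (haptoglobin) by 0.70 ± 0.65. This list had a mean of 0.37 and camera adjusted p = 0.0018, with adjusted p = 0.209 with an estimated correlation. Of 21 immediate-early and stress genes KLF2, a flow-responsive transcription factor, rose by 1.25 ± 0.23 over the list alone and 20 did not pass. Another KLF2 probe set above the filter lay at 0.28. EGR2 differed by -1.12 ± 0.78, ZFP36 by -1.05 ± 0.88 and IER2 by 0.84 ± 0.40. The list had a mean of 0.15 and camera adjusted p = 0.0401, with adjusted p = 0.399 with an estimated correlation, and leaving out GBS replicate 2, GBS replicate 4, saline replicate 3, saline replicate 4 or saline replicate 5 ended the call, with adjusted p up to 0.33, as did leaving out GBS replicate 5 and saline replicate 3 together (0.0797). Its mean was 0.08 without GBS replicate 2, 0.09 without GBS replicate 4 and 0.04 without saline replicate 5. It was 0.29 under the stricter filter and 0.27 without GBS replicate 5, saline replicate 2 and saline replicate 3.

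The endothelial, smooth muscle and cell division lists were called higher by camera at its preset correlation. Of 15 endothelial markers 3 rose when adjusted over the list alone, PECAM1 (CD31, 1.79 ± 0.53), ENG (endoglin, 1.09 ± 0.32) and SELP (P-selectin, 0.70 ± 0.21), the last named as the rest of that count. CDH5 (VE-cadherin) differed by 1.74 ± 0.71 and ICAM2 by 1.14 ± 0.46. The list had a mean of 0.61 and camera adjusted p = 1.5e-04, with adjusted p = 0.360 with an estimated correlation. Its call was lost with array weights (adjusted p = 0.212), without GBS replicate 5 and saline replicate 3 (mean 0.26, 0.0797) and with saline replicate 2 also left out (mean 0.10, 0.133). Of 12 smooth muscle markers none passed over the list alone. MYH11, smooth muscle myosin, differed by 2.32 ± 0.82, ACTG2 by 1.86 ± 0.96, SYNPO2 by 1.72 ± 0.53 and CASQ2 by -1.88 ± 0.66. That list had a mean of 0.66 and camera adjusted p = 0.0092, with adjusted p = 0.242 with an estimated correlation, and its call was lost without saline replicate 3 (adjusted p = 0.0769), under the stricter filter (0.0650), with array weights (0.0688) and with the mean of all probe sets (mean 0.38, 0.0793). It was also lost without GBS replicate 5 and saline replicate 3 (mean 0.31, 0.0801) and with saline replicate 2 also left out (mean 0.25, 0.0544). Of 18 cell division genes none passed over the list alone. TOP2A differed by 1.40 ± 0.52, CCNB1 by 1.37 ± 0.64, CCNB2 by 1.29 ± 0.61 and CDK1 by 1.04 ± 0.47. In saline animals 3 of 5 values of CCNB1 and of CDK1 and 4 of 5 of CCNB2 lay below the dim-filter level. This list had a mean of 0.57 and camera adjusted p = 4.5e-06, with adjusted p = 0.299 with an estimated correlation. In GBS replicate 5 the endothelial list stood at 0.98 and the smooth muscle list at 0.87, each the highest of the 10 arrays.

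The remaining 12 lists were not called, and 8 of them were called by camera at its preset correlation in at least 1 alternative. All 25 such calls were lost with an estimated correlation in the same setting (adjusted p = 0.142 to 0.396). Without saline replicate 2 the lists of inflammatory cytokines (mean 0.56, adjusted p = 0.0030), interferon-stimulated genes (0.49, 1.7e-05), acute phase and complement (0.37, 0.0323), class II (0.43, 0.0392) and metalloproteinases (0.30, 0.0290) were called higher. Without GBS replicate 5 acute phase and complement (0.57, 0.0168) and class II (0.61, 0.0168) were called higher and trophoblast markers lower (-0.77, 0.0128). Metalloproteinases were also called without GBS replicate 1 (0.35, 0.0354) and red cell markers without GBS replicate 3 (1.08, 0.0281). Array weights called the cytokine, acute phase, interferon-stimulated (unweighted mean 0.02, median -0.01) and class II lists higher and the trophoblast list lower, with adjusted p up to 0.0404, and from 0.260 to 0.318 with an estimated correlation. Prostaglandin genes were called only with GBS replicate 5, saline replicate 2 and saline replicate 3 all left out (-0.81, 0.0432). The inflammatory cytokines and chemokines had a mean of 0.22 over 23 genes (camera adjusted p = 0.223), which was -0.01 without GBS replicate 3, with a median of 0.16. With GBS replicate 5, saline replicate 2 and saline replicate 3 all left out the mean was 0.73 (camera adjusted p = 0.0031, or 0.233 with an estimated correlation). IL1B, IL1A, CCL5 and CCL3 differed by 1.33 ± 1.66, 1.11 ± 1.19, 1.09 ± 1.08 and 1.02 ± 1.13. Antimicrobial genes had a mean of 0.02 and a median of 0.38 over 16 genes (camera adjusted p = 0.621). Their mean ran from -0.12 without saline replicate 3 to 0.20 without GBS replicate 5. It was also below 0 without GBS replicate 3, GBS replicate 4 or saline replicate 4, with arrays centred on their median or quantile normalization repeated, and under the stricter filter (-0.19). DEFB1 (beta-defensin 1) differed by -2.20 ± 0.91, WFDC2 by -1.94 ± 1.07 and PTX3 (pentraxin 3) by -1.94 ± 0.83, and S100A9 is also on this list. Of 14 acute phase and complement genes CFB, complement factor B, fell by 2.49 ± 0.63 over the list alone and 13 did not pass. Its probe sets disagreed, at -2.49, 0.24 and -1.54. CFP (properdin) differed by 1.62 ± 0.68, C1QA by 0.78 ± 0.53 and C1QB by 0.70 ± 0.48, and the list mean was 0.25 (camera adjusted p = 0.235), against 0.08 without GBS replicate 1 and 0.10 under the stricter filter. Interferon-stimulated genes had a mean of 0.02 and a median of -0.01 (camera adjusted p = 0.927), and the camera direction was down, against the sign of the mean. Leaving out 1 array, the mean ran from -0.19 without saline replicate 5 to 0.49 without saline replicate 2. It was also below 0 without GBS replicate 3, GBS replicate 4, saline replicate 1 or saline replicate 4 and with the same rescalings. With GBS replicate 5, saline replicate 2 and saline replicate 3 all left out it was 0.71 (camera adjusted p = 4.8e-10, or 0.214 with an estimated correlation). The direction of this list was therefore not settled. GBP1 differed by 0.79 ± 1.27, GBP2 by -0.78 ± 1.01, IFIT1 by -0.59 ± 1.01 and IFI44 by 0.51 ± 0.57. Class II antigen presentation had a mean of 0.24 (camera adjusted p = 0.322), which was -0.0032 without saline replicate 3, with CTSS at 0.65 ± 0.60 and the class II genes MAMU-DRA at 0.64 ± 0.71, MAMU-DQA1 at -0.62 ± 0.89 and MAMU-DMA at 0.51 ± 0.54.

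The rest of the lists not called include markers of B and plasma cells, decidual stroma, trophoblast and red cells. B and plasma cell markers had a mean of 0.42 over 5 genes (camera adjusted p = 0.343), with JCHAIN at 0.87 ± 0.97, FCRLA at 0.69 ± 0.60, CD22 at 0.56 ± 0.43 and BLK, a B cell kinase, at -0.10 ± 0.12. Of 16 decidual stroma markers WNT4 fell by 1.57 ± 0.34 over the list alone, HOXA10 differed by 1.12 ± 0.70, PRLR by 0.72 ± 0.63 and BMP2 by 0.68 ± 0.44, and the list mean was 0.18 (camera adjusted p = 0.621). That mean was -0.15 without saline replicate 3, 0.54 without GBS replicate 5 and -0.0098 with both of these and saline replicate 2 left out. Trophoblast markers had a mean of -0.32 over 19 genes (camera adjusted p = 0.343), against -0.09 without saline replicate 3. GATA3 differed by -2.62 ± 0.90, PLAC8 by 2.57 ± 0.71, XAGE3 by -1.99 ± 1.54 and PLAC1 by 1.84 ± 1.55, the last with GBS replicate 5 at 13.5 against at most 5.36 on the other 9 arrays. Red cell markers had a mean of 0.73 over 5 genes (camera adjusted p = 0.178), which was 0.0086 without GBS replicate 5, with HBA at 1.59 ± 1.06, HBG2, fetal haemoglobin, at 0.97 ± 1.95, ALAS2, a haem synthesis enzyme of red cells, at 0.67 ± 0.48 and HBB at 0.23 ± 0.57. Matrix metalloproteinases and inhibitors had a mean of 0.28 over 24 genes (camera adjusted p = 0.111), from 0.13 without saline replicate 3 to 0.44 without GBS replicate 5. MMP3 differed by 2.39 ± 1.33, MMP1 by 2.20 ± 1.15, SERPINE2 by -1.78 ± 0.94 and PLAUR by -0.97 ± 0.78. Prostaglandin and labour-associated genes had a mean of -0.40 over 9 genes (camera adjusted p = 0.323), which was -0.60 without GBS replicate 5, with PLA2G2A at -2.39 ± 1.43, HPGD, the prostaglandin-degrading enzyme, at -1.53 ± 1.29, CRH, corticotropin-releasing hormone, at 0.50 ± 0.27 and PTGES3 at 0.42 ± 0.36. Mesenchymal transition genes had a mean of 0.12 over 14 genes (camera adjusted p = 0.335), from 0.06 without saline replicate 3 to 0.22 without GBS replicate 5, with S100A4 at -1.33 ± 0.47, ZEB2 at 0.78 ± 0.34, WNT5A at 0.75 ± 0.23 and TGFB3 at 0.72 ± 0.52. Without the filter on dim probe sets the means of the B cell, trophoblast, red cell and prostaglandin lists were 0.26, -0.18, 0.45 and -0.26. Under the stricter filter those of the trophoblast, metalloproteinase and prostaglandin lists were -0.58, 0.12 and -0.61.

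**Figure D3:**
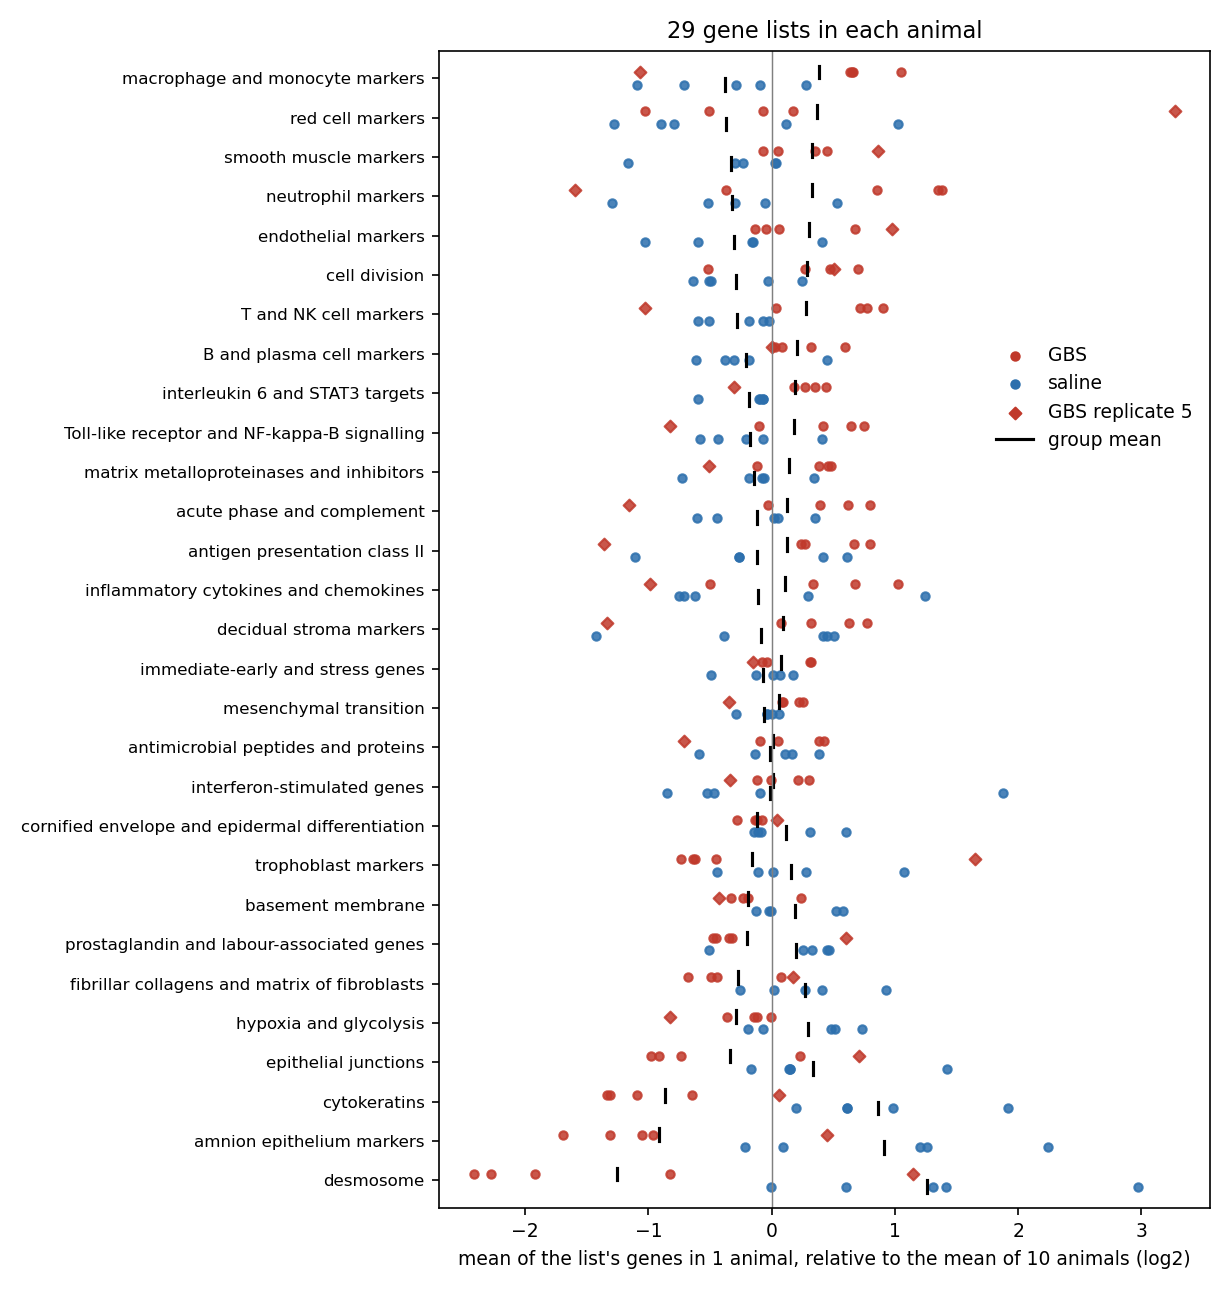
Mean of each of the 29 gene lists in each animal relative to the mean of the 10 animals (log2, horizontal axis), 1 point per animal, with group means as black bars and GBS replicate 5 as a diamond. The cytokeratin list of all 5 GBS animals lies below that of every saline animal, and GBS replicate 5 stands at 1.65 for trophoblast and 3.27 for red cell markers.

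Across all genes no single gene passed. With limma 0 of 10044 genes and 0 of 26383 probe sets passed an adjusted p of 0.05, against 723 genes (353 higher and 370 lower after GBS, 502 expected by chance) and 1872 probe sets at an unadjusted p under 0.05. An unequal-variance test per gene also called 0, with 606 genes at an unadjusted p under 0.05. Among the 723 genes, 61 were at least 4-fold lower after GBS and 5 at least 4-fold higher. In 166 genes (1.65%) the groups did not overlap, 98 with GBS below and 68 with GBS above, where chance gives 0.794% on average. Genes are correlated across the arrays, so that share can vary between groupings of the animals, which was not tested for it. Without saline replicate 3 the count of genes passing was 4, and without saline replicate 4 it was 2. With array weights it was 26. Without both arrays that stood apart on the first component, GBS replicate 5 and saline replicate 3, a choice made after seeing the data, 16 genes passed, 14 lower and 2 higher, and KRT24 (-5.99 ± 0.66), KRT3 (-4.91 ± 0.56), DSC2 (-4.23 ± 0.49) and CD8A (1.23 ± 0.13) were among them.

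The 14 genes with the smallest p among those lower after GBS did not pass, with adjusted p from 0.0558 to 0.286. They were led by LOC718942, an unnamed locus at -5.25 ± 0.61, and include KRT24, KRT3, ITGB6 and P4HA2. F2RL1, the protease-activated receptor 2, differed by -2.30 ± 0.39, and SLC27A6, a fatty acid transporter, by -4.24 ± 0.75. PCTP, a phosphatidylcholine transfer protein, differed by -2.86 ± 0.47, with a second probe set at 0.09. NDUFA4L2, a mitochondrial protein induced in low oxygen, differed by -2.90 ± 0.53 and TMPRSS7, a membrane serine protease, by -3.01 ± 0.60. ZBED2 differed by -4.48 ± 0.78, SHISA2 by -2.74 ± 0.44, SPAG4 by -2.47 ± 0.37 and LNPK by -1.02 ± 0.18. In 13 of these 14 genes every GBS animal lay below every saline animal. All 5 GBS values of TMPRSS7 and 4 of 5 of SLC27A6 and ZBED2 lay below the dim-filter level, so the size of these differences is uncertain. Over all 135 named genes 4 had every value of 1 group there, TMPRSS7 and WNT4 after GBS and ATP8B4 and SYNPO2 after saline, and 20 more had 3 or 4 values of a group there. After GBS these were KRT24, KRT3, ZBED2, SLC27A6, CLDN1, DSG2, EPCAM, GABRP, HAND1, SFN, TP63 and ZFP36. After saline they were SLC35G2, CCNB1, CCNB2, CDK1, IL1A and JCHAIN, and in both groups FCRLA and HBG2. The size of their differences is uncertain too.

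The 14 genes with the smallest p among those higher after GBS did not pass either, with adjusted p from 0.173 to 0.457. KMO, kynurenine 3-monooxygenase of tryptophan breakdown, differed by 1.08 ± 0.19, and KLF2, CD8A, IL6R and PLAC8 are also among the 14. NR1H3, the liver X receptor alpha, differed by 1.63 ± 0.43, ABCC3, an organic anion exporter, by 1.65 ± 0.43 and PRCP, a lysosomal carboxypeptidase, by 1.01 ± 0.22. GSDME, a gasdermin, differed by 1.40 ± 0.38, DAB2, an endocytic adaptor, by 1.30 ± 0.35 and GIMAP8 by 1.04 ± 0.27. AEBP1 differed by 1.48 ± 0.37, and the remaining 2, SLC35G2 and ATP8B4, by 1.5 ± 0.38 and 1.62 ± 0.44. In 8 of the 14 the groups did not overlap. Of the 135 genes the rule named, 56 had several probe sets above the filter, and in 7 of those (CFB, ENG, KRT3, MS4A7, P4HA1, PCTP and TNFAIP2) these differed in sign. In others the sign agreed but another probe set lay much nearer 0, as in LAMA3 (-0.14), DSG2 (-0.03), LOXL2 (-0.09) and KLF2 (0.28). Such genes were not counted.

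Over all lists 27 members passed when adjusted over the list alone, 21 lower and 6 higher, and 17 of 29 lists were called by camera, 8 lower and 9 higher. With an estimated correlation 0 lists were called, with adjusted p from 0.198 to 0.530 for those 17 and 6 lists at an unadjusted p under 0.05. By fry for a shift in 1 direction (directional fry) and by the exact permutation test 0 were called, with 6 and 5 lists at an unadjusted p under 0.05. Fry for members moving in either direction called 1 list, the cytokeratins (adjusted p = 0.0056), and says nothing of their direction. The permutation test could hardly call a list here. The cytokeratin list, at the smallest p that test can give (0.00794), adjusted to 0.230 over the 29 lists, so the count of 0 by that test decides little. The count of members was 17 without GBS replicate 2 or without saline replicate 3, and 75 without GBS replicate 5.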

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

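The tests of GBS replicate 5 and of the leukocyte lists were chosen only after the results were seen, as were, for the cytokeratins, the comparison with the endothelial list, the comparison of other lists with all 13 measured members, the agreement of probe sets and the sizes of the control ratios, and all differences between list means without 1 array. A value was picked out when 1 animal lay far from the other 4 of its group, by its gap to the nearest over the group's whole range. Chance marks about 1 in 20 groups. This occurred in 39 of 358 groups of values, where chance gives about 18 if the values were independent, which genes and lists of 1 array are not. Of the 39, GBS replicate 5 had 25.

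GBS replicate 5 stood apart at 73.5 on the first principal component (next GBS array -20.2) and at 50.3 on the second (next 10.8). Its scores, in log2 units against the mean of 10 arrays, were high for the trophoblast list (1.65), the red cell list (3.27) and the prostaglandin list (0.60), and low for the macrophage list (-1.07), class II presentation (-1.36) and mesenchymal transition (-0.35). Its log2 levels were high for PLAC1 (13.46), HBG2 (13.78), PLA2G2A (13.25), XAGE3 (12.33), IGF2BP3 (12.18), S100A2 (10.84), TFAP2A (10.69), GABRP (10.40), GATA3 (10.04), ICAM2 (9.35), FCRLA (7.78), ALAS2 (7.71) and TP63 (6.77). They were low for CD14 (7.75), C1QB (8.87), MAMU-DRA (9.52) and MAMU-DMA (7.04).

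For that array, trophoblast and fetal blood in the tissue piece is a candidate explanation, since its trophoblast score of 1.65 and its red cell score were both the highest of the 10 arrays, with PLAC1 at 13.46 and HBG2 at 13.78. Of the 19 trophoblast and 5 red cell markers measured, 0 are on another list, but how many the chorion itself expresses was not tested. Degraded RNA stays open as a part of it, since 2 of the 3 control genes had their highest 3' to 5' ratio in this array. A wrong group label stays open too: of 75 genes with an unadjusted p under 0.001 without this array, it lay nearer to the saline mean in 73.3%, while of 7 cytokeratins called without it, it lay nearer to the GBS mean in 4 and below every saline animal in 5. A biological difference of this animal was not tested.

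Saline replicate 2 had a high interferon-stimulated score (1.88) and high GBP1 (12.43), CCL5 (9.29), TOP2A (7.89) and TGM3 (7.96), with a low prostaglandin score (-0.51) and low HPGD (6.83). Saline replicate 3 had a high epithelial junction score (1.42) and high CFB (11.82) and TP63 (8.03), with low smooth muscle (-1.17) and interleukin 6 and STAT3 (-0.60) scores and low ICAM2 (5.55). It shared several traits of GBS replicate 5, with trophoblast at 1.07, red cell at 1.03, macrophage at -1.09 and class II at -1.11. Its ACTB 3' to 5' log2 ratio was 3.16, against 3.30 in GBS replicate 5. On the second component these arrays lay apart, at -28.3 and 50.3. Saline replicate 1 had high JCHAIN (8.11).

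For the fall of the cytokeratins, dilution by leukocytes would lower other cell types alike. The cytokeratin mean minus the endothelial mean per animal differed by -2.342 ± 0.522 (SE, n = 5 per group, exact permutation p = 0.00794, the smallest possible, and from -2.69 to -1.90 without 1 array). That gap cannot decide it, since the endothelial list was itself higher after GBS (mean 0.61). Whether leukocytes express its members was not tested. Against the decidual stroma mean the gap was -1.91 ± 0.87 (exact permutation p = 0.0556, and from 0.0159 without GBS replicate 5 to 0.111 without other arrays). Dilution by leukocytes therefore stays open. A group difference in RNA quality stays open: the control ratios separated the groups for 0 of 3 control genes and differed by 0.22 ± 0.20 for GAPDH, -0.07 ± 0.26 for ACTB and -0.10 ± 0.08 for EF1A, but the overlap set beforehand as the bound does not exclude a partial difference. Probes shared between keratin paralogs stay open too, since only 1 family, type I, had a called member whose probe sets agreed in sign, and the type II call rests on the doubted probe set of KRT3, which makes the bound set beforehand, called members of both families, wrong here. A lower share of epithelium in the piece cannot be told apart from a fall within epithelial cells, which the inoculation or the day could bring. Relative to the median of all 13 cytokeratins that of the amnion markers lay at -0.662 ± 0.651, desmosome genes at -1.30 ± 0.50 and epithelial junctions at 0.98 ± 0.41, so these epithelial lists lay on both sides. These ± values, and those in the next sentence, are SDs over 1000 bootstrap draws of the arrays within each group. For epithelium the bound set beforehand, against the 5 called cytokeratins alone, was exceeded and would have excluded that explanation (junctions 3.13 ± 0.58, amnion markers 1.49 ± 0.46), but it was wrong because those 5 were selected for their fall while the other lists were whole.

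The higher leukocyte lists may reflect the makeup of the piece. More decidua stays open, since the macrophage mean minus the decidual stroma mean differed by 0.585 ± 0.341 (SE, n = 5 per group, exact permutation p = 0.151), from 0.35 without saline replicate 5 to 0.74 without saline replicate 3, and the decidual mean itself changed sign without saline replicate 3. A lower share of epithelium, leaving more of every other type, also stays open: the macrophage mean minus the fibroblast matrix mean differed by 1.312 ± 0.605 (exact permutation p = 0.0714), but minus the trophoblast mean by 1.08 ± 0.95 (exact permutation p = 0.294). Both rest on GBS replicate 5, without which they were 1.79 ± 0.40 and 1.90 ± 0.50 (exact permutation p = 0.0159 and 0.0238). The first of these values would argue against this explanation. The second would do so only if trophoblast is not counted as epithelium, since the trophoblast mean itself was lower without that array (-0.77). Without saline replicate 3 the second was 0.68 ± 0.89, and without saline replicate 4 the first had exact permutation p = 0.0476. The inoculation, and the day confounded with it, stay among the open explanations.

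Of the 126 distinct splits of the arrays into 5 and 5, 100 were drawn, the real one included. The real counts of genes and probe sets were 0, which all 100 splits reach by construction, so the splits say nothing about chance for them (highest others 5 and 14). As many as the 723 genes at an unadjusted p under 0.05 came from 23 splits (highest other 1729), and as many as the 27 list members from 6 (highest other 100), so chance cannot be excluded for these. For the 17 lists called by camera, 4 of the 100 splits, the real one included, gave as many (highest other 20). That share lies under 0.05, the bound set beforehand, for this 1 of 5 counts only. It has no adjustment over the 5 and holds at the preset correlation only. The splits not drawn could move it past 0.05, so chance is not excluded here either. The count of called lists was 0 with an estimated correlation, with directional fry and with the exact permutation test, and it was 12 without saline replicate 3. Which arrays stood together in the splits with 20 lists or 1729 genes was not examined, so the source of those counts was not tested.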

How the results depend on the processing

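The fits without arrays that stood apart and with a tissue covariate were chosen after seeing the data. The cause of the changes below was not tested unless stated. The cytokeratin mean stayed negative and called by camera under the other filters, scalings, variance settings, weights and probe set rule, from -2.51 with the stricter filter to -0.68 without a filter, and from -1.96 (without GBS replicate 5) to -1.47 (without saline replicate 3) leaving out 1 array. It kept its value of -1.73 but lost its call with an estimated correlation (adjusted p = 0.198) and with directional fry (0.0885). The exact permutation test gave it an adjusted p of 0.230, from the smallest p that test can give. The count of called lists was 0 in all 3. Leaving out 1 array gave 0 to 4 genes (4 without saline replicate 3, 2 without saline replicate 4), 0 to 5 probe sets (1 and 5 without the same arrays), 497 (without GBS replicate 2) to 1194 (without GBS replicate 5) genes at an unadjusted p under 0.05, 17 (without GBS replicate 2 or saline replicate 3) to 75 (without GBS replicate 5) list members and 12 to 21 lists. The stricter filter, which tests fewer genes, gave 1 gene, 3 probe sets, 456 genes at an unadjusted p under 0.05 and 9 lists of 24 tested, since 5 lists, 3 of them called otherwise (desmosome, amnion epithelium, cell division), kept too few members to test, and the cornified envelope mean turned to 0.16 (adjusted p = 0.860). Array weights gave 26 genes, 7 probe sets, 1660 genes at an unadjusted p under 0.05 and 121 members, with low weights for GBS replicate 5 (0.22), saline replicate 2 (0.276) and saline replicate 3 (0.392). Without GBS replicate 5 and saline replicate 3 there were 16 genes, 25 probe sets and 71 members. With saline replicate 2 also left out there were 36 genes, 9 probe sets, 1398 genes at an unadjusted p under 0.05 and 103 members. With the trophoblast minus decidua score as a covariate there were 5 genes (KRT24, KRT3, LOC718942, CD8A and LOC694628, the last named after its value was seen), 6 probe sets and 1136 genes at an unadjusted p under 0.05, and camera was not run. At an unadjusted p under 0.05 with a fold of at least 1.5, a looser threshold, there were 462 genes (218 higher, 244 lower) and 1149 probe sets. For the other 28 lists, 609 alternative values held 502 on the same side of the threshold, 81 that lost a call, 25 that gained one and 1 reversed. Of the 135 genes the rule named, 127 kept their sign in every alternative, 8 changed it at least once without passing, and 19 passed in at least 1. Signal over background was not known for single probe sets, so which dim genes carry signal could not be judged.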

Other observations

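The fits reported here leave out arrays and were chosen after seeing the data, as were the genes. TFAP2A, an AP-2 transcription factor, and IGF2BP3, an RNA-binding protein of fetal tissue, did not pass over all 10 arrays, at -1.98 ± 1.39 (SE, limma adjusted p = 0.863) and -2.96 ± 1.37 (limma adjusted p = 0.715), each on its brightest probe set. In both genes GBS replicate 5 was high, at 10.69 and 12.18, while the other 4 GBS animals lay from 3.58 to 3.79 for TFAP2A and from 4.32 to 5.65 for IGF2BP3, below every saline animal. Without GBS replicate 5 and saline replicate 3, TFAP2A differed by -2.74 ± 0.34 and IGF2BP3 by -3.87 ± 0.42 (limma adjusted p = 0.0332 and 0.0315). GATA3 differed by -2.77 ± 0.35 in that fit (limma adjusted p = 0.0332). With saline replicate 2 also left out the 3 genes still passed, at -2.62 ± 0.36, -3.62 ± 0.41 and -2.87 ± 0.38 (limma adjusted p = 0.0470, 0.0402 and 0.0402), in fits that omit animals because of where they lay.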
